A study of Danio rerio with 24 samples.

How the data were processed

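RNA was measured in 24 pools of zebrafish material on Affymetrix zebrafish arrays. The groups cross 2 genotypes (wild type and the young mutant), 2 tissues (dissected retina and whole embryo) and 2 ages (36 and 52 hpf), with 3 arrays in each of 8 groups. Per the labels, a pool held 10 embryos or 10 retinas (20 retinas of 10 embryos for mutant retinas at 36 hpf), and 33 ng of RNA was amplified by two-cycle labelling. The deposited table holds 1 intensity per probe set and array, on a linear scale from 0 to 20110. How the authors summarised probes and scaled arrays is not given in the sources used here. The other deposited text records of each array, a kind of file with no expression values, were used only for the order of hybridization days, the fluidics station and module, and recorded wash errors.

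Of 15617 probe sets 115 controls were removed and 15502 tested. The platform annotation gave 1 gene symbol for 10795 probe sets, several for 135 and none for 4572, in all 8793 distinct symbols. Gene names were brought up to date by gene ID with the RefSeq annotation of the GRCz12tu assembly, which changed 1 symbol, and the same annotation gave the neighbours of smarca4a. The lowest correlation between 2 arrays of a group was 0.9722. Retina arrays had lower medians and more probe sets listed at 0 than embryo arrays.

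The rule for scaling, fixed before the data were examined, called for quantile normalization where medians of arrays differed by more than 0.1 on the log2 scale. It applied, so intensities were quantile normalized over all 24 arrays and converted to log2(value + 16). A linear model with 1 mean per group (16 residual degrees of freedom, prior degrees of freedom 4.25) was fitted with limma 3.58.1 in R 4.3.3, and 15 contrasts were taken from it, which were 4 for genotype, 4 for time, 2 for tissue and 5 interactions. The p-values are moderated, two-sided and adjusted by Benjamini and Hochberg over all probe sets of a contrast, with a threshold of 0.05. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

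Genes were named by a rule fixed before the data were examined: smarca4a in each contrast; up to 10 genes each way (5 for interactions) with the largest difference among those past the threshold that have 1 symbol and, for contrasts of 2 groups, no overlap of the 3 arrays against the other 3; and up to 4 members of each list with the largest change. Names of uncharacterised clones were counted, not printed.

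The 18 lists of genes, fixed before the data were examined, covered retinal progenitors, the Notch pathway, retinal ganglion cells, photoreceptors, amacrine, bipolar and horizontal cells, Müller glia, synapse, cell cycle, the SWI/SNF complex, p53 and apoptosis, immediate early and stress genes, lens, pigment cells and retinal pigment epithelium, muscle, blood, liver, gut and yolk, skin and skeleton, and ribosomal proteins. A further 3 lists, of FGF feedback and target genes, of brain regions outside the eye and of glucocorticoid response, were written after the results had been seen. Some genes stand on more than 1 list. Each list was tested with camera, with a preset correlation between genes of 0.01 and 1 probe set per gene (the brightest), and adjusted over the 18 lists of a contrast. The 3 later lists were tested in the same way but adjusted over those 3 alone. Counts of members past the threshold are over all probe sets or, where said, adjusted over the list alone.

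Replicate numbers were checked for pairing. After group means were removed, arrays of the same number in different groups correlated with a median of 0.331, against -0.169 for other numbers, and each of the 24 arrays had its best match in its own number. The number followed the hybridization day (days 1, 2 and 3), except that WT embryo 52 hpf replicate 3 was hybridized alone on day 4. A model with the replicate number as a block was therefore run beside the one reported, and list medians were also taken within each day. The fluidics station differed between the genotypes on every array, so station and genotype cannot be told apart. Each combination of tissue and age likewise had its own fluidics module on every array. The module therefore cannot be told apart from tissue and age in the time and tissue contrasts. Each of the 8 groups had its own pair of station and module. This pair cannot be told apart from the group in the interactions either. A wash error was recorded for yng retina 36 hpf replicate 1.

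The pipeline was tested on simulated data with 200 changed probe sets. In the genotype contrast of retinas at 52 hpf it recovered 34.3%, 89.6% and 100% of changes of 0.5, 1 and 2 on the log2 scale, with 6 false calls; in the interaction of genotype and time in retinas 4.48%, 61.2% and 98.5%, with 6 false calls; and in the interaction of all 3 factors 0%, 16.4% and 89.4%, with 4 false calls. With no change simulated, the genotype contrast of retinas at 36 hpf gave 0 calls. The simulated noise was independent between arrays and lacked the replicate effect described above, so these rates may differ in the real data.

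The alternatives were the intensities as deposited, a log offset of 1, leaving out the dimmest 40% of probe sets, a variance trend with robust moderation, only the groups of a contrast in the fit, the replicate block, the hybridization day as a block, a per-probe-set linear model without moderation and the same with backward elimination of terms (the kind of model that the series description names), a minimum of 2-fold, and leaving out each array in turn; for lists, camera with an estimated correlation, fry and all probe sets of a gene. The array with a wash error and the array alone on its day were left out together as an alternative chosen after the data were seen. Arrays were also regrouped in all 10 splits of each contrast of 2 groups and in 100 splits for each interaction, and by swaps within pairs of the same replicate number with the block (4 splits, 32 for the interactions of 2 factors and 100 for all 3). No test of single deviating arrays was run.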

Results

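The transcriptomes of dissected retinas and whole zebrafish embryos were measured in wild-type (WT) animals and in young (yng) mutants at 36 and 52 hours post fertilization (hpf). The yng mutation lies in smarca4a, also called brg1, which encodes the ATPase of the SWI/SNF chromatin remodelling complex. The set comprised 24 one-colour Affymetrix zebrafish arrays in 8 groups of 3, formed by crossing genotype, tissue and age. Each array was hybridized with RNA from a pool of 10 embryos or 10 retinas, except that the yng retina pools at 36 hpf held 20 retinas from 10 embryos. Each value is a probe set intensity from 0 to 20110, with medians of 221 to 239 in the whole-embryo arrays and 144 to 163 in the retina arrays. Arrays have no sequencing depth, and their number limits the precision. The median standard deviation within a group was between 0.149 and 0.199 on the log2 scale. Differences are log2 differences of normalized intensity ± SE with n = 3 arrays per group, and adjusted p is limma's, over 15502 probe sets. The SE is the model's, from a moderated variance shared by all 8 groups. It can be too small where the groups compared vary more than the others, as for irx4a at 36 hpf and cryba4 at 52 hpf in retinas. The p-values measure the spread between arrays of pools, not between single animals. That spread includes the effect shared by arrays of the same replicate number, which the model reported does not remove.

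The smarca4a transcript was lower in yng than in WT in both tissues at both ages. The difference for probe set Dr.2414.1.S2_at was -1.61 ± 0.08 in retinas at 52 hpf and -1.68 ± 0.08 at 36 hpf. In embryos it was -2.06 ± 0.08 at 52 hpf and -2.08 ± 0.08 at 36 hpf, with adjusted p from 1.25e-13 to 9.69e-12. A dimmer probe set for smarca4a, Dr.2414.1.S1_at, gave -1.74, -1.58, -1.74 and -1.76 in the same order. In the brighter probe set the deposited intensity was 3134 to 4158 in the 12 WT arrays and 756.6 to 1251 in the 12 yng arrays. Between 36 and 52 hpf the level of smarca4a did not pass in any genotype and tissue with the model used. The brighter probe set did pass in yng retinas with the replicate block, where it was 0.162 higher at 52 hpf (adjusted p = 0.0441), and on the intensities as deposited (0.225). For the brighter probe set, the fall was smaller in retinas than in embryos by 0.46 ± 0.11 at 52 hpf (adjusted p = 0.0102) and by 0.41 ± 0.11 at 36 hpf (adjusted p = 0.0488). Neither difference passed on the intensities as deposited, and the dimmer probe set gave 0.01 and 0.18.

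**Figure D1:**
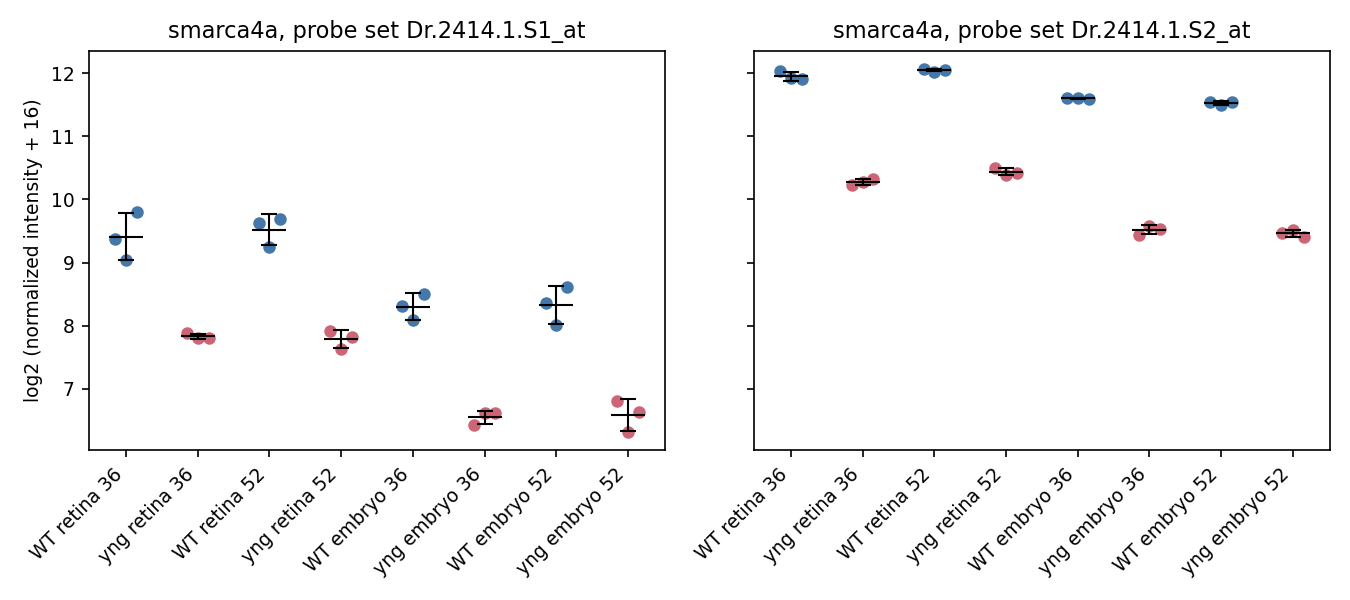
Log2 (normalized intensity + 16) of smarca4a in each of the 24 arrays, for 2 probe sets. Points are arrays (blue WT, red yng), and bars give the mean and SD of the 3 arrays in each of the 8 groups. In each tissue and at each age every yng array lies below every WT array.

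Genotype was first compared in retinas at 52 hpf, the age at which WT retinal cells are differentiating. Among the largest falls in yng were those of lrrc4.1 (Dr.14757.1.A1_at), which encodes a synaptic adhesion protein (-3.92 ± 0.23), calb2b (Dr.11068.1.A1_at), a calretinin gene (-3.79 ± 0.20), and nrxn1a, a neurexin (-3.43 ± 0.36). They also included neurod6a, a neuronal transcription factor (-3.39 ± 0.18), and pvalb6, a parvalbumin (-3.28 ± 0.16). The gene for rod transducin, gnat1, fell by 3.14 ± 0.23 in 1 probe set (Dr.9899.1.S2_at) and by 0.91 in the other. The caveolar gene cavin2a, 210 to 286 in WT, was listed at 0 in all 3 yng arrays. Among genes higher in yng were cryba4 (Dr.15802.2.S1_a_at, 4.02 ± 0.61) and crybb1 (3.60 ± 0.57), lens crystallins. Others were arg2, an arginase (2.91 ± 0.28), baiap2a, a regulator of actin (2.89 ± 0.18), and the transcription factors atf5a (2.82 ± 0.21) and sox21b (2.71 ± 0.34). The crystallin gene crygmxl2 and the midbrain-hindbrain transcription factor gene en2b were listed at 0 in all 3 WT arrays and reached 17.9 to 617 and 61.6 to 77.8 in yng. Adjusted p for these genes ran from 5.1e-17 to 0.00104. For the genes chosen by size in this and the other comparisons of 2 groups, the 3 arrays of one group all lay above the 3 of the other, which chance gives for 10% of genes.

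By fixed list, 13 of 19 measured retinal ganglion cell genes fell at 52 hpf and none rose (1 rose adjusted over the list alone). The falls included irx4a (-2.69 ± 0.27), stmn2a (-2.07 ± 0.20), gap43 (-2.04 ± 0.18) and the axon guidance receptor robo2 (-2.03 ± 0.17). The list's median was -1.17 (camera adjusted p = 8.58e-11). Of 18 synapse genes 13 fell, or 14 with 1 that rose adjusted over the list alone, with a median of -1.24 (adjusted p = 2.46e-10). Among them syt1a, the calcium sensor of vesicle release, fell by 2.71 ± 0.20 and complexin cplx2a by 2.33 ± 0.41. Of 23 genes of amacrine, bipolar and horizontal cells 12 fell (median -0.60, adjusted p = 4.15e-08), among them slc32a1, the transporter of inhibitory transmitters (-2.57 ± 0.30). Of 42 photoreceptor genes 15 fell, or 16 adjusted over the list alone, and 3 rose (median -0.16, adjusted p = 2.19e-04). The falls included those of gngt1 (-2.14 ± 0.17) and rcvrn2, a recoverin gene (-1.99 ± 0.21). Of 11 Müller glia genes 6 fell (1 rose adjusted over the list alone), led by rlbp1a (-2.84 ± 0.15), a carrier of visual-cycle retinoids. The list's median was -0.33 (adjusted p = 0.00331, but adjusted p = 0.0667 with an estimated correlation). Cell cycle genes went the other way. Of 47 measured, 26 rose and none fell, or 34 adjusted over the list alone, with a median of 0.43 (adjusted p = 2.09e-10). The rises included ccne1 (1.03 ± 0.30), ccnd1 (0.81 ± 0.14) and cdc45 (0.78 ± 0.14).

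The other fixed lists did not pass as groups in retinas at 52 hpf. Of 13 lens genes 4 rose, cryba4, crygmxl2, crybb1 and crygm2c, and each stood far lower in yng replicate 3 than in the other two. The list's median was 0.21 (adjusted p = 0.0511, and 0.0218 on the intensities as deposited). Of 20 Notch pathway genes 5 rose, among them the ligand dla (1.13 ± 0.11), and hey1 fell by 1.31 ± 0.13 (adjusted p = 0.266). Of 21 retinal progenitor genes 3 rose, led by ascl1a (1.24 ± 0.14), and 7 fell (adjusted p = 0.254). Of 33 immediate early and stress genes 12 rose, including atf3 (1.73 ± 0.18), and 7 fell, including junba (-2.72 ± 0.31), with adjusted p = 0.266. Of 26 p53 and apoptosis genes 8 rose and 3 fell, the latter led by tp53inp1 (-1.39 ± 0.12), with adjusted p = 0.322. Of 33 genes of liver, gut and yolk 7 fell and 1 rose (adjusted p = 0.0615), the falls led by the apolipoprotein genes apobb.1 (-2.59 ± 0.37) and apoa2 (-1.67 ± 0.20). In the SWI/SNF list of 12, smarca4a fell and arid2 rose (0.59 ± 0.16), with adjusted p = 0.9 for the list. The lists of tissues that a dissection could carry over gave adjusted p of 0.809 for pigment cells (3 of 14 rose, 1 fell) and 0.809 for muscle (2 of 35 rose, 1 fell). They gave 0.99 for blood (1 of 22 rose, 3 fell) and 0.809 for skin and skeleton (3 of 33 rose, 2 fell). Of 69 ribosomal protein genes 1 rose (adjusted p = 0.809). For the muscle, blood, skin and ribosomal lists the median, mean and test differed in sign.

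In all, 3057 probe sets passed in retinas at 52 hpf, 1553 higher and 1504 lower in yng, and 796 of them differed by at least 2-fold, 226 higher and 570 lower. With the replicate number as a block, which pairs arrays hybridized on 1 day, 4818 passed. The gapdh 3'/5' log2 ratio, a sign of RNA quality, was higher in yng retinas than in WT by a mean of 0.359 at 52 hpf, where the neuronal lists were lower. On days 1, 2 and 3 taken alone the median of the ganglion cell list was -1.20, -0.86 and -1.18, and that of the synapse list -1.28, -1.10 and -1.26. On the same days the median of the photoreceptor list was -0.21, -0.15 and -0.22, and that of the cell cycle list 0.49, 0.45 and 0.39.

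In yng retinas at 36 hpf the largest fall was in irx4a (Dr.25775.1.S1_at), an Iroquois transcription factor (-4.66 ± 0.27), followed by inab, a neuronal intermediate filament (-3.35 ± 0.19). Next were tmsb, a thymosin (-3.25 ± 0.20), and adcyap1b, which encodes a neuropeptide precursor (-3.22 ± 0.15). Further falls included genes of synaptic vesicles, with syt1a at -2.88 ± 0.20, sypa, a synaptophysin, at -2.84 ± 0.30, sv2bb at -2.83 ± 0.21 and cplx2a at -2.69 ± 0.41. The last did not pass with only the retina groups at 36 hpf in the fit. Higher in yng were fzd8b (Dr.8181.1.S1_at), a Wnt receptor (2.16 ± 0.20), rcn3, a calcium-binding protein of the endoplasmic reticulum (1.96 ± 0.27). So were the growth factor gene mdkb (1.64 ± 0.24), etv4, a transcription factor of FGF signalling (1.62 ± 0.23), and fgf8a (1.54 ± 0.18). Adjusted p for these genes ran from 1.59e-11 to 0.000153.

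In the fixed lists at 36 hpf, 12 of 19 ganglion cell genes fell (median -0.79, adjusted p = 2.55e-15). Among them were stmn2a (-2.61 ± 0.20), the chemokine receptor cxcr4b (-2.25 ± 0.21) and gap43 (-2.25 ± 0.18), which marks growing axons. Of 18 synapse genes 11 fell, or 13 with 1 that rose adjusted over the list alone (median -0.92, adjusted p = 2.5e-11). Of 21 retinal progenitor genes 7 rose and 2 fell, or 11 and 3 adjusted over the list alone (median 0.29, adjusted p = 1.74e-04). The rises included those of rx3 (0.97 ± 0.14) and six6a (0.90 ± 0.14), both eye-field transcription factors, while sox19a fell by 1.22 ± 0.35. The cell cycle list had 1 member that rose, gmnn (0.47 ± 0.11), and a median of 0.14 (adjusted p = 0.00134, but adjusted p = 0.46 with an estimated correlation). Of 22 blood genes 6 fell, or 8 adjusted over the list alone, led by lcp1 (-1.22 ± 0.20), a leukocyte actin-bundling protein, and slc4a1a (-1.07 ± 0.23), the red cell anion exchanger. The list had a median of -0.20 (adjusted p = 0.00134, but adjusted p = 0.29 with an estimated correlation). Photoreceptor genes did not pass as a group (5 of 42 fell, adjusted p = 0.422), nor did Müller glia (4 of 11 fell, adjusted p = 0.0743) or amacrine, bipolar and horizontal cells (5 of 23 fell and 2 rose, adjusted p = 0.0754). Of 33 immediate early and stress genes 9 rose and 5 fell (adjusted p = 0.0743).

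A total of 1408 probe sets passed in retinas at 36 hpf, 649 higher and 759 lower in yng, 342 of them by at least 2-fold (88 higher, 254 lower). With the replicate block 2865 passed, and with only the groups of this contrast in the fit 331. The gapdh 3'/5' log2 ratio differed by a mean of -0.222 between yng and WT retinas at 36 hpf. By day, the ganglion cell median was -1.20, -0.89 and -0.63, the synapse median -1.06, -0.97 and -0.59, and the progenitor median 0.31, 0.25 and 0.28. Of the probe sets past the threshold at both ages in retinas, 361 were higher and 523 lower in yng both times, against 65 and 73.6 for independent lists, and 26 went opposite ways. Across probe sets, which are not independent replicates, the differences at the 2 ages correlated with r = 0.573.

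Genotype was also compared in whole embryos, which include the eyes. At 52 hpf the largest falls in yng included those of capn2l (Dr.10119.1.A1_at), a calpain gene (-3.22 ± 0.16), anxa1b, an annexin (-3.22 ± 0.23), and crabp1a, a binding protein of retinoic acid (-2.62 ± 0.22). They were followed by arl3l1 (-2.55 ± 0.20) and sst6.1, a somatostatin gene (-2.40 ± 0.18). Higher were hbaa1, a globin gene (2.46 ± 0.45), baiap2a (Dr.16661.1.A1_at, 2.3 ± 0.18), slc37a4b, a transporter of glucose 6-phosphate (2.2 ± 0.21). Also higher were cav1, the caveolin gene (1.98 ± 0.24), and mmp9, a matrix metalloproteinase (1.95 ± 0.25), while hbaa1 did not pass with a log offset of 1. At 36 hpf capn2l (-2.95 ± 0.16), aebp1b (-2.68 ± 0.20), fkbp5, a co-chaperone of steroid receptors (-2.65 ± 0.20), and col28a2a, a collagen (-2.48 ± 0.21), fell. At that age s100b (2.88 ± 0.18), the nuclear receptor gene nr0b2a (2.39 ± 0.24), slc37a4b (2.03 ± 0.21), baiap2a (1.94 ± 0.18) and the photoreceptor transcription factor crx (1.60 ± 0.16) rose. Adjusted p for these genes ran from 3.96e-11 to 0.00148. The nsfa gene, which encodes an ATPase of membrane fusion, gave 2.27 ± 0.21 and 1.89 ± 0.21 in probe set Dr.9155.1.S1_at, while in retinas at 52 hpf that probe set of nsfa rose (1.58) and its other probe set, Dr.9155.2.A1_at, fell (-1.05, adjusted p = 0.016). Probe set Dr.24966.1.S1_at of the hormone receptor gene mchr1b was listed at 0 in all 12 yng arrays of both tissues and at 55.7 to 237 in WT. The other probe set of mchr1b, Dr.24966.1.A1_at, was dim and did not pass in any of the 4 contrasts (-0.062 to 0.183).

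The list of immediate early and stress genes passed upward in yng embryos, but at neither age with an estimated correlation. At 52 hpf 6 of 33 rose and none fell, or 10 and 1 adjusted over the list alone. The gene atf3 stood at 1.2 ± 0.18, and the cytokine-signalling inhibitors socs3b and socs3a at 1.16 ± 0.19 and 1.04 ± 0.17. The list had a median of 0.28 (adjusted p = 1.19e-05, but adjusted p = 0.149 with an estimated correlation). At 36 hpf 7 rose and 2 fell, or 10 and 2 adjusted over the list alone, including txnipa (0.84 ± 0.18). The median was 0.36 (adjusted p = 0.00359, but adjusted p = 0.349 with an estimated correlation). The list's median was 0.15, 0.31 and 0.37 by replicate number at 52 hpf, where the third pair joined days 3 and 4. By day at 36 hpf it was 0.36, 0.36 and 0.26. In embryos at 52 hpf the synapse list (2 of 18 fell, median -0.26, adjusted p = 0.00127) and the list of amacrine, bipolar and horizontal cells (3 of 23 fell, median -0.31, adjusted p = 0.00951) also passed. So did the skin and skeleton list (5 of 33 fell and 2 rose, median -0.12, adjusted p = 0.00951) and the blood list (2 of 22 rose, median 0.19, adjusted p = 0.013). With an estimated correlation the adjusted p of these 4 was 0.373, 0.328, 0.328 and 0.373. The gapdh 3'/5' log2 ratio was higher in yng than in WT embryos by a mean of 0.257 at 52 hpf and 0.074 at 36 hpf. Without yng embryo 52 hpf replicate 3 the blood list gave 0.0586, and without replicate 2 of that group the skin and skeleton list gave 0.0503. At 36 hpf the progenitor list had a median of 0.14 with 2 of 21 genes higher (adjusted p = 0.0382, but adjusted p = 0.116 with an estimated correlation), and gave 0.0539, 0.0842 and 0.1 without WT embryo replicate 2, WT embryo replicate 3 or yng embryo replicate 3 of that age. The ganglion cell list did not pass in embryos at 52 hpf (adjusted p = 0.295) or 36 hpf (adjusted p = 0.624).

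In embryos 915 probe sets passed at 52 hpf, 430 higher and 485 lower (212 by at least 2-fold, 2116 with the replicate block, 603 without yng embryo 52 hpf replicate 3). At 36 hpf 922 passed, 431 higher and 491 lower (155 by at least 2-fold, 2247 with the block, 449 with only the groups of the contrast in the fit, 590 without WT embryo 36 hpf replicate 2). Of the probe sets past the threshold at both ages in embryos, 222 were higher and 252 lower both times, against 12 and 15.4 for independent lists, and 2 went opposite ways (r = 0.687 across probe sets). Retina and embryo shared 240 higher and 250 lower at 52 hpf, with 20 opposite. At 36 hpf they shared 181 higher and 160 lower, with 8 opposite. A total of 186 probe sets, 95 higher and 91 lower, passed in the same direction in all 4 genotype comparisons. Among them were slc37a4b (1.16 to 2.2), s100b (0.98 to 2.88) and ndrg4 (-2.19 to -1.58). They also included hsd11b2, which encodes a cortisol-inactivating enzyme (-2.48 to -1.25), and the sugar-phosphate enzyme gene pgls. For pgls 1 probe set gave -2.43 to -1.96, while another of the 186 gave only -0.712 to -0.531. On the chromosome of smarca4a in the GRCz12tu assembly lie 14 other genes with probe sets among these 186, including mchr1b, pgls, nsfa, baiap2a and cyp3c3.

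**Figure D2:**
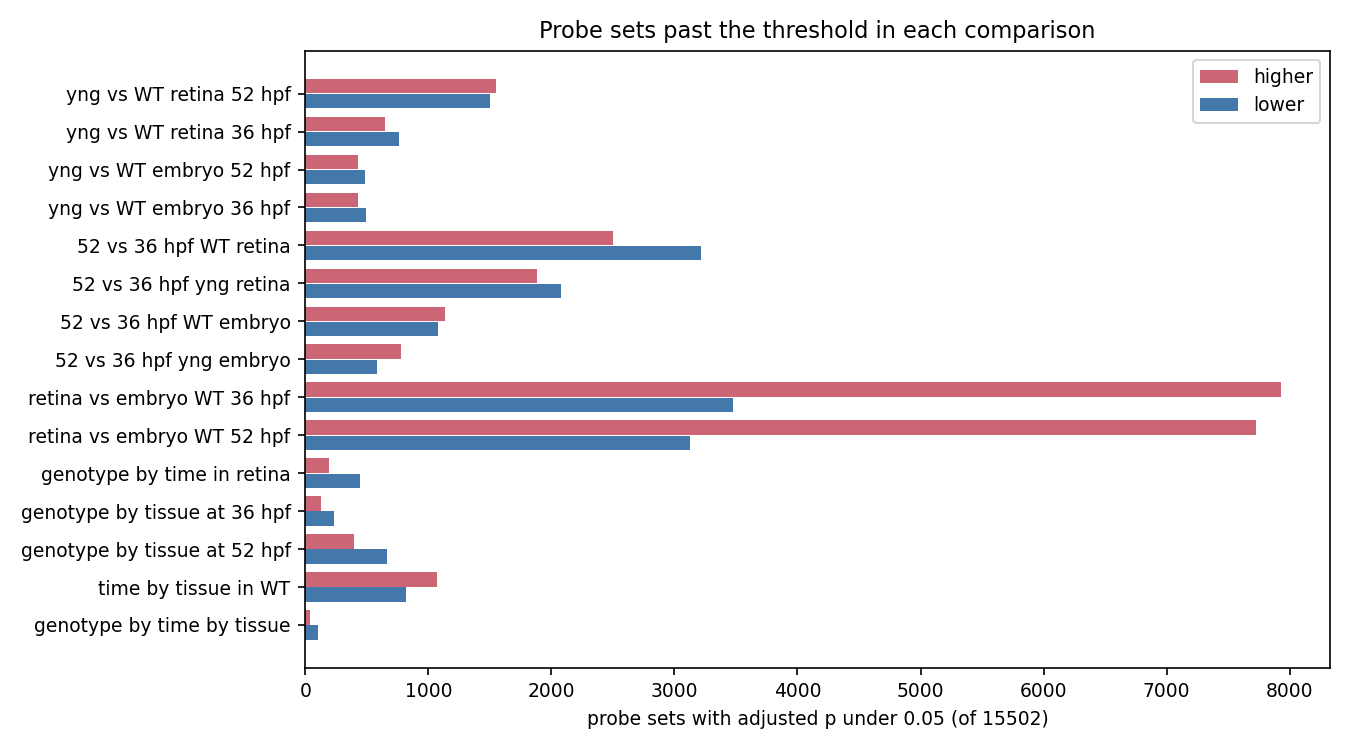
Number of probe sets, of 15502, with adjusted p under 0.05 in each of 15 comparisons. Red bars count probe sets higher and blue bars those lower in the first-named group (for interactions, a positive or negative difference); the comparisons of retina with embryo reach 11408 and 10854 probe sets and the interaction of all 3 factors 135.

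The next comparisons ask how the retina matures between 36 and 52 hpf in each genotype. In WT retinas the largest rises included those of calb2b (6.02 ± 0.20), gng13b, a G protein subunit (5.59 ± 0.21), and cntn1b, a neural adhesion protein (5.29 ± 0.16). They also included rcvrn2 (5.22 ± 0.21), the mitochondrial creatine kinase gene ckmt2a (4.99 ± 0.15) and prom1b, a photoreceptor membrane protein (4.54 ± 0.19). The transporter that loads acetylcholine into vesicles, slc18a3a, was listed at 0 in all 3 arrays at 36 hpf and reached 353 to 406 at 52 hpf. The embryonic globin gene hbbe3 (-3.23 ± 0.34), sox19a (-2.51 ± 0.35) and sp8b (-2.27 ± 0.21) fell. In yng retinas rcvrn2 (4.33 ± 0.21), ckmt2a (4.55 ± 0.15) and gng13b (4.16 ± 0.21) rose too, beside sv2bb (4.90 ± 0.21), sypb (4.60 ± 0.27) and irx4a (4.24 ± 0.27). In the same comparison fzd8b (-2.58 ± 0.20), the chemokine gene cxcl12a (-2.46 ± 0.24), the Wnt inhibitor gene sfrp1a (-2.43 ± 0.22) and etv4 (-2.29 ± 0.23) fell. Adjusted p for these genes ran from 8.78e-16 to 6.24e-06.

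In WT retinas 16 of 18 synapse genes rose (median 2.06, adjusted p = 7.54e-12), as did 16 of 23 genes of amacrine, bipolar and horizontal cells (median 1.77, adjusted p = 3.23e-10). So did 21 of 42 photoreceptor genes, with 1 that fell (median 0.54, adjusted p = 3.23e-10), and 11 of 19 ganglion cell genes, with 2 that fell (median 0.83, adjusted p = 1.98e-06), led by isl2a (3.69 ± 0.24). Of 47 cell cycle genes 38 fell, or 41 adjusted over the list alone (median -0.85, adjusted p = 1.6e-11). Of 20 Notch pathway genes 12 fell (median -0.68, adjusted p = 3.53e-04), led by her2 (-2.08 ± 0.18). In yng retinas the synapse list rose by a median of 1.90 (15 of 18 genes, adjusted p = 8.44e-14) and the ganglion cell list by 0.65 (11 of 19, 2 fell, adjusted p = 6.32e-08). The list of amacrine, bipolar and horizontal cells rose by 0.62 (12 of 23, adjusted p = 2.29e-06) and the photoreceptor list by 0.16 (17 of 42, 2 fell, adjusted p = 2.02e-07). The cell cycle list fell in yng retinas by a median of 0.485, with 26 of 47 genes lower or 31 adjusted over the list alone (adjusted p = 6.32e-08, but adjusted p = 0.108 with an estimated correlation). The Notch list fell by 0.253, with 6 of 20 lower (adjusted p = 0.017, but adjusted p = 0.15 with an estimated correlation). Of the 270 tests of fixed lists in the 15 comparisons 95 passed, with median, mean and test in 1 direction in each, and 42 of the 95 also passed with an estimated correlation.

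In WT retinas 5720 probe sets passed between the ages, 2500 higher and 3220 lower at 52 hpf, 1574 of them by at least 2-fold. In yng retinas 3969 passed, 1887 higher and 2082 lower, 1085 by at least 2-fold. The gapdh 3'/5' log2 ratio changed by a mean of -0.393 with age in WT retinas and by 0.188 in yng retinas, so this sign of RNA quality moved with age and with genotype by time. The share that was higher depended on the scaling, at 43.7% in WT and 47.5% in yng after quantile normalization and 58.0% and 57.9% on the intensities as deposited. Of probe sets past the threshold in both genotypes 1549 rose and 1643 fell in both, against 304 and 432 for independent lists, and 39 went opposite ways (r = 0.806 across probe sets). The 1034 probe sets that rose at least 2-fold in WT had a median of 1.68 in WT and 1.21 in yng, and 850 of them passed in yng. The 540 that fell at least 2-fold had a median of -1.18 in WT and -0.89 in yng, and 444 passed in yng. Both sets were chosen by their change in WT, which by itself favours a smaller median in yng.

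**Figure D3:**
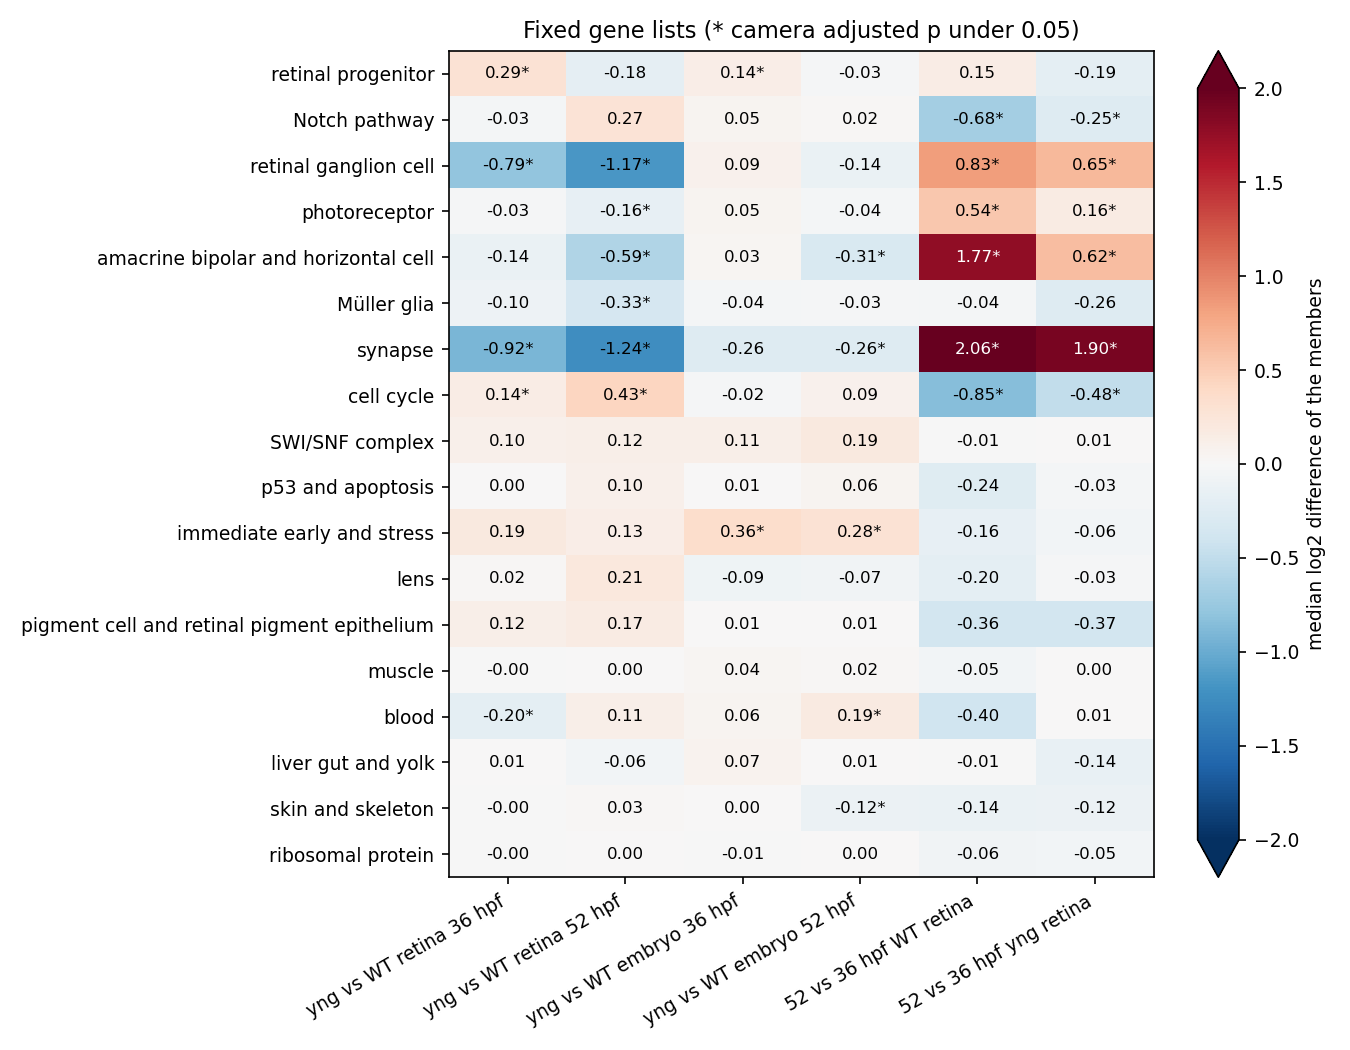
Median log2 difference of the members of each of 18 fixed lists (vertical axis) in 6 comparisons (horizontal axis). Red is higher and blue lower in the first-named group, each cell prints its median, and an asterisk marks a camera adjusted p under 0.05; in yng retinas at 52 hpf the ganglion cell and synapse lists stand at -1.17 and -1.24 and the cell cycle list at 0.43.

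In whole embryos the time comparison showed several transcription factor genes of the eye rising. In WT embryos col10a1a (Dr.4697.1.S1_at), a collagen of bone and cartilage, rose by 5.99 ± 0.27. The photoreceptor transcription factors crx, six7 and otx5 rose by 3.31 ± 0.16, 3.20 ± 0.26 and 2.71 ± 0.20, and the bipolar cell factor vsx1 by 2.99 ± 0.25. In the same embryos acp5a, a phosphatase of osteoclasts and macrophages (-2.56 ± 0.21), the cathepsin gene ctss2.1 (-2.94 ± 0.31) and oc90, an otoconial protein (-1.87 ± 0.20), fell. In yng embryos six7 (2.80 ± 0.26), vsx1 (2.71 ± 0.25), agt, the angiotensinogen gene (2.57 ± 0.15), and nr2e3 (2.21 ± 0.20) rose. There acp5a (-2.49 ± 0.21), the apolipoprotein gene apoa4a (-1.38 ± 0.16) and s100b (-1.32 ± 0.18) fell, while col10a1a went from 0 in all 3 arrays to 320 to 704. Adjusted p for these genes ran from 7.02e-12 to 5.69e-05.

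Of 47 cell cycle genes 38 fell in WT embryos (41 adjusted over the list alone; median -0.61, adjusted p = 1.16e-20) and 31 in yng embryos (40 adjusted over the list alone; median -0.52, adjusted p = 8.66e-24). The synapse list rose by a median of 0.66 in WT (9 of 18, or 16 adjusted over the list alone; adjusted p = 3.5e-10) and 0.62 in yng (7 of 18, or 11; adjusted p = 2.2e-10). The photoreceptor list rose by 0.15 (12 of 42 rose, 1 fell, adjusted p = 1.38e-07) and 0.09 (11 rose, 2 fell, adjusted p = 2.55e-06). The list of amacrine, bipolar and horizontal cells rose by 0.82 in WT (11 of 23, adjusted p = 1.73e-08) and 0.39 in yng (4 of 23, 1 fell, adjusted p = 4.74e-04, but adjusted p = 0.081 with an estimated correlation). Notch genes fell by 0.255 in WT (7 of 20, adjusted p = 0.00275, but adjusted p = 0.0793 with an estimated correlation) and by 0.416 in yng (4 of 20, or 9 adjusted over the list alone; adjusted p = 1.06e-04). Ganglion cell genes rose in WT (6 of 19, 2 fell, median 0.37, adjusted p = 6.69e-04, but adjusted p = 0.0593 with an estimated correlation). In yng embryos they gave adjusted p = 0.0496, and the lens list 0.0496 with crygm2c and bfsp2 higher. Their adjusted p was 0.262 and 0.331 with an estimated correlation, and 0.0788 and 0.102 with the replicate block. Leaving out any array of the yng embryo groups except 52 hpf replicate 1 ended the ganglion cell call (0.0519 to 0.105), and leaving out yng embryo 36 hpf replicate 1 or 3, or 52 hpf replicate 1 or 3, ended the lens call (0.0719 to 0.083). The immediate early and stress list rose in yng embryos (5 of 33, 2 fell, median 0.15, adjusted p = 0.00758, but adjusted p = 0.259 with an estimated correlation). Skin and skeleton genes rose in WT (4 of 33, 1 fell, median 0.15, adjusted p = 0.00322, but adjusted p = 0.0903 with an estimated correlation). Blood genes fell in WT (6 of 22, median -0.18, adjusted p = 0.0363, but adjusted p = 0.357 with an estimated correlation and 0.124 with the replicate block, and 0.0521, 0.0534 and 0.0712 without WT embryo 36 hpf replicate 2, 36 hpf replicate 3 or 52 hpf replicate 2). Between the ages 2221 probe sets passed in WT embryos, 1138 higher and 1083 lower at 52 hpf (374 by at least 2-fold, 3893 with the block). In yng embryos 1369 passed, 782 higher and 587 lower (232 by at least 2-fold, 2775 with the block, 787 without yng embryo 36 hpf replicate 3). The share that was higher was 51.2% in WT and 57.1% in yng embryos after quantile normalization and 60.5% and 68.1% on the intensities as deposited. Both genotypes shared 610 that rose and 447 that fell, with 3 opposite. The gapdh 3'/5' log2 ratio changed by a mean of -0.237 with age in WT embryos and by -0.054 in yng embryos.

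The comparison of WT retina with WT embryo asks which transcripts mark the dissected eye. Muscle and skin transcripts were nearly absent from the retina pools: myhz1.3 (Dr.23067.1.S1_at), a myosin heavy chain gene, was 12768 to 13086 in embryos at 36 hpf and listed at 0 in all 3 retina arrays. In retinas pvalb2 of muscle, myl1 and mylz3 were likewise listed at 0 at both ages. Higher in the retina at 36 hpf were the transcription factors six7 (Dr.12825.1.A1_at, 3.78 ± 0.26), crx (3.73 ± 0.16), otx5 (3.73 ± 0.20), nr2e3 (3.56 ± 0.20), vsx1 (3.52 ± 0.25) and pax6b (3.10 ± 0.16). Higher at 52 hpf were guk1b (3.83 ± 0.16), the cone transducin subunit genes gngt2b (3.66 ± 0.22) and gngt2a (3.48 ± 0.28), ckmt2a (3.64 ± 0.15), rcvrn2 (3.53 ± 0.21) and the eye-field factor rx2 (3.25 ± 0.15). The muscle list was lower by a median of -6.60 at 36 hpf and -6.42 at 52 hpf (34 of 35 genes each time, adjusted p = 4.45e-33 and 4.57e-34). The skin and skeleton list was lower by -4.69 and -5.28 (29 and 30 of 33, adjusted p = 9.15e-21 and 2.21e-25), and the liver, gut and yolk list by -4.30 and -3.82 (21 and 22 of 33, adjusted p = 1.91e-10 and 4.42e-12). Progenitor genes were higher by 1.51 and 1.35 (15 and 17 of 21, adjusted p = 9.47e-04 and 1.21e-04). Photoreceptor genes were higher by 0.61 and 1.13 (31 and 38 of 42, adjusted p = 0.00163 and 1.03e-07; at 36 hpf adjusted p = 0.0776 with an estimated correlation). Cell cycle genes were higher by 0.98 and 0.91 (46 and 45 of 47, adjusted p = 6.13e-08 and 9.2e-07), but adjusted p = 0.0776 and adjusted p = 0.107 with an estimated correlation. Blood genes were lower by -1.48 and -1.34 (adjusted p = 7.89e-05 and 1.45e-05) and Müller glia genes by -1.57 and -1.41 (adjusted p = 0.00163 and 0.00162). For blood adjusted p = 0.0776 and 0.0549 and for Müller glia adjusted p = 0.0691 and 0.0549 with an estimated correlation.

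After quantile normalization the median of all probe sets was 0.39 higher in WT retinas than in WT embryos at 36 hpf and 0.37 higher at 52 hpf, against -0.08 and -0.02 on the intensities as deposited. A difference in this comparison is relative to that shift. The count was 11408 at 36 hpf, 7929 higher and 3479 lower, and 7887 as deposited, 2633 higher and 5254 lower. At 52 hpf it was 10854, 7725 higher and 3129 lower, and 7043 as deposited, 2606 higher and 4437 lower. The smarca4a probe set Dr.2414.1.S2_at was higher in retina by 0.35 at 36 hpf, which did not pass as deposited (0.08), and by 0.52 at 52 hpf. Lists of smaller change also moved with the setting: immediate early and stress genes (adjusted p = 0.0264 at 36 hpf and 0.00893 at 52 hpf), pigment cell genes (0.0288 and 0.00633) and lens genes (0.0161 at 52 hpf) were lower in retina. Synapse genes were lower at 36 hpf (median -1.34, adjusted p = 1.50e-04), and genes of amacrine, bipolar and horizontal cells were higher at 52 hpf (adjusted p = 0.0428). None of these passed with an estimated correlation, at adjusted p = 0.26, 0.177, 0.271, 0.177, 0.181, 0.183 and 0.232 in that order. The list of amacrine, bipolar and horizontal cells at 52 hpf also gave 0.0616 with the replicate block and 0.0958 with all probe sets of a gene. As deposited the immediate early and pigment cell lists gave 0.0866 and 0.104 at 36 hpf. With all probe sets of a gene the former gave 0.192 and 0.174 at the 2 ages and the latter 0.0712 at 36 hpf.

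The interactions test whether a difference itself differs. In retinas, the genotype difference changed between 36 and 52 hpf for 637 probe sets, 194 upward and 443 downward (358 by at least 2-fold, 1406 with the block, 384 with only the retina groups in the fit). The change was downward for calb2b (-3.70 ± 0.28), pvalb6 (-3.55 ± 0.23) and bhmt, a methyltransferase of homocysteine metabolism (-3.35 ± 0.42 in 1 probe set, 0.032 in the other). These were lower in yng at 52 hpf and did not pass at 36 hpf (-0.093, 0.263 and 0.48). It was also downward for junba, an immediate early transcription factor (-3.85 ± 0.44), which was higher in yng at 36 hpf (1.13, adjusted p = 0.0249) and lower at 52 hpf. The transcription factor gene sox21b moved upward (2.55 ± 0.49), though not with only the retina groups in the fit. Genes of amacrine, bipolar and horizontal cells moved down as a group (7 of 23, median -0.53, adjusted p = 3.38e-06). So did progenitor genes (6 of 21, with 1 upward, median -0.33, adjusted p = 6.07e-05), among them mdkb (-2.16 ± 0.34). The photoreceptor list also moved down (8 of 42, with 2 upward, median -0.15, adjusted p = 2.30e-04, but adjusted p = 0.0774 with an estimated correlation). The cell cycle list moved up with no member passing alone (median 0.30, adjusted p = 5.77e-06, but adjusted p = 0.197 with an estimated correlation). The blood list moved up (1 of 22, median 0.24, adjusted p = 0.00602) and the liver, gut and yolk list down (4 of 33, median -0.03, adjusted p = 0.00602). With an estimated correlation they gave adjusted p = 0.313 and adjusted p = 0.14, and the blood list gave 0.0511 without yng retina 52 hpf replicate 2. The ganglion cell and synapse lists did not pass in this test (adjusted p = 0.654 and 0.337), although irx4a moved upward by 1.98 ± 0.39.

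The genotype difference differed between retina and embryo for 367 probe sets at 36 hpf (131 upward, 236 downward, 235 by at least 2-fold, 816 with the block, 184 with only the groups of the contrast in the fit) and 1061 at 52 hpf (396 upward, 665 downward, 580 by at least 2-fold, 1971 with the block). At 36 hpf irx4a (-4.61 ± 0.39), inab (-3.09 ± 0.27) and adcyap1b (-3.05 ± 0.22) were lower in yng retinas and did not pass in yng embryos. The genes aebp1b (2.60 ± 0.29) and fkbp5 (2.34 ± 0.29), lower in yng embryos, moved the opposite way. At 52 hpf the genotype difference was more negative in the retina for neurod6a (-2.66 ± 0.26), junba (-3.03 ± 0.44) and bhmt (-2.92 ± 0.42), and cryba4 (4.09 ± 0.86) and crybb1 (3.63 ± 0.81) were more raised there. The ganglion cell list was lower in the retina by -1.02 at 36 hpf (10 of 19, adjusted p = 2.34e-23) and -0.91 at 52 hpf (10 of 19, adjusted p = 1.51e-12). The list of amacrine, bipolar and horizontal cells was lower by -0.39 at 52 hpf (6 of 23, adjusted p = 7.36e-07). The synapse list stood at -0.67 and -0.75 (6 and 8 of 18 lower, 1 higher each time, adjusted p = 2.99e-07 and 5.64e-07), but adjusted p = 0.158 and adjusted p = 0.112 with an estimated correlation. At 52 hpf the cell cycle list (4 of 47 up, median 0.37, adjusted p = 2.5e-08), the photoreceptor list (7 of 42 down, 1 up, adjusted p = 1.68e-04) and the lens list (4 of 13 up, adjusted p = 0.0129) also passed. With an estimated correlation they stood at adjusted p = 0.112, 0.0751 and 0.244, and the lens list gave 0.0686 with the replicate block. At 36 hpf blood genes (3 of 22 down, median -0.54, adjusted p = 1.55e-06), genes of amacrine, bipolar and horizontal cells (2 of 23 down) and cell cycle genes (both adjusted p = 0.0146) passed. With an estimated correlation they stood at adjusted p = 0.0991, 0.253 and 0.532, and the cell cycle list gave 0.0744 as deposited. Without WT retina 36 hpf replicate 1 or yng retina 36 hpf replicate 2 the list of amacrine, bipolar and horizontal cells gave 0.341 and 0.0541. The cell cycle list gave 0.0584 to 0.18 without WT retina replicate 1 or 2, WT embryo replicate 3, yng embryo replicate 1 or yng retina replicate 3 of that age.

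The change with age in WT differed between retina and embryo for 1892 probe sets, 1071 upward and 821 downward (890 by at least 2-fold, 3210 with the block), and the upward share was 56.6% after quantile normalization and 67.8% as deposited. The rise was larger in retina for calb2b (4.86 ± 0.28), nexn, which encodes an actin-binding protein (4.50 ± 0.18), ndrg1a (4.37 ± 0.28) and the mitochondrial creatine kinase gene ckmt1 (4.17 ± 0.35), and larger in embryos for col10a1a (-6.66 ± 0.38). Synapse genes (10 of 18 up, 1 down, median 1.23, adjusted p = 8.05e-08) and genes of amacrine, bipolar and horizontal cells (8 of 23 up, 2 down, 0.605, adjusted p = 8.45e-06) rose more in retina. So did ganglion cell genes (7 of 19 up, 0.55, adjusted p = 2.65e-05) and photoreceptor genes (12 of 42 up, 4 down, 0.19, adjusted p = 5.21e-04). With an estimated correlation the synapse and photoreceptor lists both gave adjusted p = 0.0873. Notch (3 of 20, adjusted p = 0.0291), lens (4 of 13, adjusted p = 0.0352) and skin and skeleton genes (9 of 33, adjusted p = 0.00406) moved down. With an estimated correlation they stood at adjusted p = 0.224, 0.308 and 0.121. Without WT embryo 52 hpf replicate 3 or WT retina 36 hpf replicate 1 the Notch list gave 0.0745 and 0.171. The lens list gave 0.0534 to 0.0937 without either of these arrays, WT retina 36 hpf replicate 3 or WT retina 52 hpf replicate 2, and 0.097 with the block.

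The interaction of all 3 factors passed for 135 probe sets, 35 upward and 100 downward (131 by at least 2-fold, 292 with the block). With a log offset of 1 the count was 72, and without the dimmest 40% of probe sets 75. It was downward for pvalb6 (-3.26 ± 0.32) and bhmt (-3.40 ± 0.60) and upward for irx4a (3.10 ± 0.55), anxa1b (2.70 ± 0.46) and rasd1, a small GTPase gene (2.33 ± 0.32), with adjusted p from 8.82e-06 to 0.00488. The list of amacrine, bipolar and horizontal cells (3 of 23 down, median -0.12, adjusted p = 0.0395) and the cell cycle list (no member alone, median 0.23, adjusted p = 0.00196) passed. Both gave adjusted p = 0.382 with an estimated correlation. The former gave 0.117 with the block, and 0.0533 to 0.153 on leaving out WT embryo 36 hpf replicate 1, WT retina 36 hpf replicate 3, WT retina 52 hpf replicate 1 or 2, yng embryo 36 hpf replicate 1, yng embryo 52 hpf replicate 1 or 2, or yng retina 36 hpf replicate 1.

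**Figure D4:**
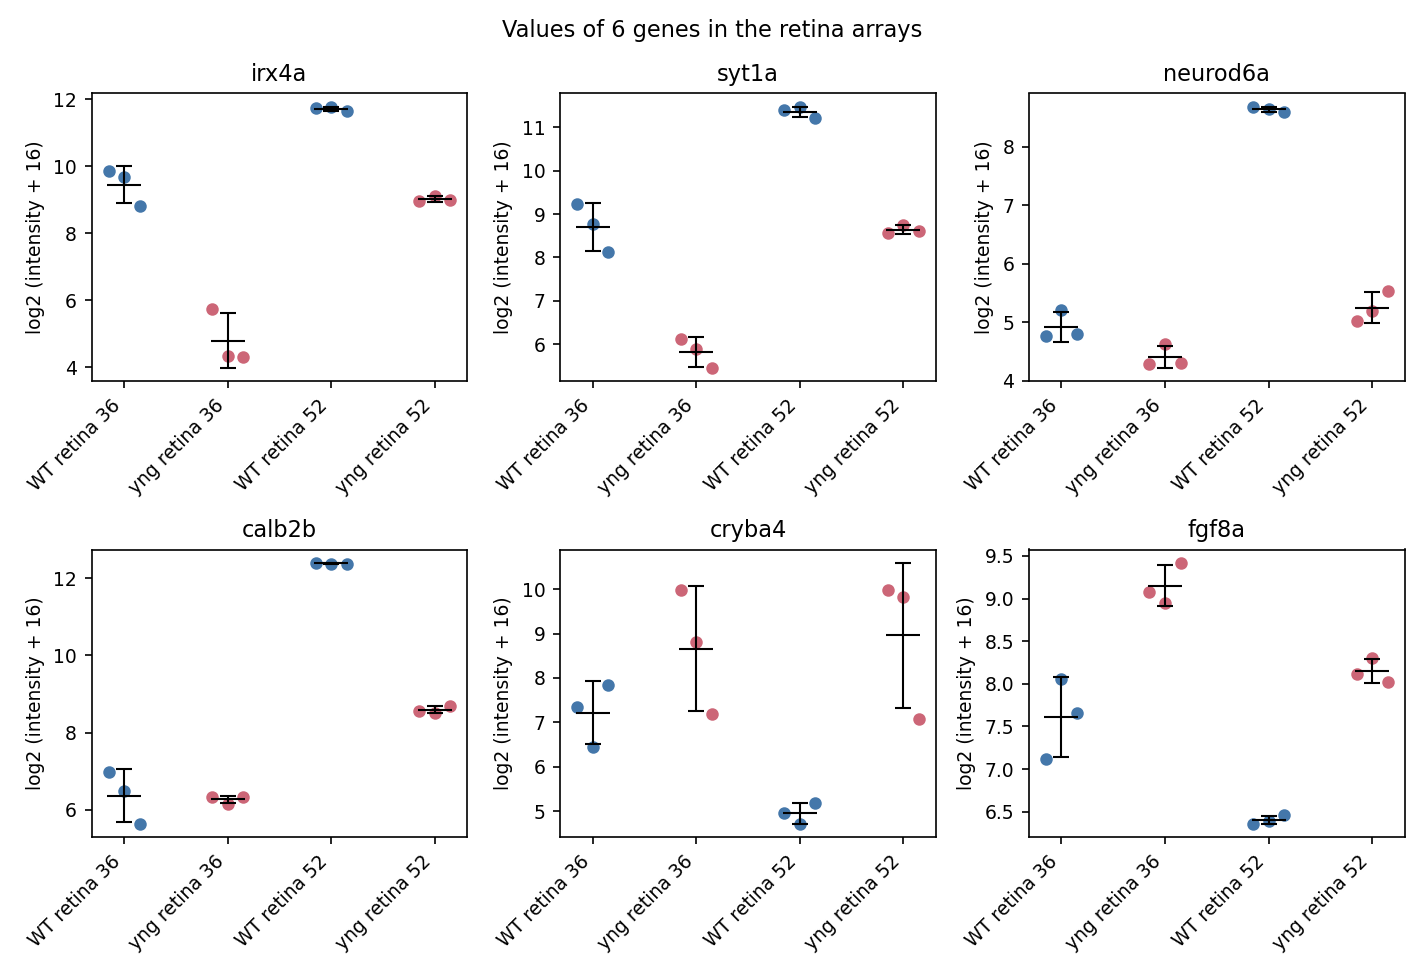
Log2 (normalized intensity + 16) of irx4a, calb2b, syt1a, neurod6a, cryba4 and fgf8a in the 12 retina arrays. Points are arrays (blue WT, red yng) and bars give the mean and SD of the 3 arrays in each group; yng minus WT is -4.66 for irx4a at 36 hpf and -3.79 for calb2b at 52 hpf.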

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

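The tests of the smarca4a chromosome, of the neighbourhood and the station, of lens cells, of RNA quality and carried-over tissue, of a delay, the splits for the 5 interactions and the swaps within pairs were chosen only after the result was seen; the splits of the 10 contrasts of 2 groups were set before.

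A difference between groups was tested directly, as an interaction, in 5 contrasts, and each result named with an interaction value in the next 2 paragraphs is listed because that test passed. The counts were 637 for genotype by time in retina, 367 and 1061 for genotype by tissue at 36 and 52 hpf, 1892 for time by tissue in WT and 135 for all 3 factors. Among 100 splits of the arrays, with lower-order effects subtracted first, 1 gave as many probe sets, the real one. The highest of the others gave 139, 249, 1, 541 and 2 in that order. A share of 1 in 100 is under 0.05, which argues against chance for each count as a whole, not for each probe set in it. The splits cannot separate an interaction from an effect of fluidics station and module. The real interaction stayed in the regrouped values, which adds spread and can lower the counts of the other splits. Those splits leave the pairing by replicate number aside. With the replicate block and only swaps within pairs, 1 of 32 splits (1 of 100 for all 3 factors), the real one, gave as many. The real counts were 1406, 816, 1971, 3210 and 292, and the highest of the others 169, 74, 8, 508 and 21. In the 10 contrasts of 2 groups 10 splits cannot give a share under 0.05. For genotype the real and highest other counts were 3057 and 1 (retina 52 hpf), 1408 and 28 (retina 36 hpf), 915 and 1 (embryo 52 hpf) and 922 and 0 (embryo 36 hpf). For time they were 5720 and 6 (WT retina), 3969 and 7 (yng retina), 2221 and 0 (WT embryo) and 1369 and 0 (yng embryo), and for tissue 11408 and 0 at 36 hpf and 10854 and 0 at 52 hpf. Swaps within pairs make 4 splits here, and with the block the highest other count was 29 for genotype in retinas at 36 hpf and 0 elsewhere.

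In the test of genotype by time in retina the log2 values were 3.90 for crygmxl2, 3.10 for olig3, 2.95 for crygm2c, 2.55 for sox21b, -4.02 for cavin2a, -3.85 for junba, -3.70 for calb2b, -3.55 for pvalb6 and -3.35 for bhmt; those of olig3, crygmxl2, crygm2c and sox21b did not pass with only the retina groups in the fit. For genotype by tissue at 36 hpf they were 2.95 for capn2l, 2.60 for aebp1b, 2.48 for col28a2a, 2.34 for fkbp5, 2.18 for ctsll, -4.61 for irx4a, -3.09 for inab, -3.05 for adcyap1b, -2.88 for tmsb and -2.64 for sypa, and at 52 hpf 4.09 for cryba4, 3.84 for crygmxl2, 3.63 for crybb1, -3.89 for cavin2a, -3.03 for junba, -2.92 for bhmt, -2.85 for hbaa1 and -2.66 for neurod6a. For time by tissue in WT they were 4.86 for calb2b, 4.50 for nexn, 4.37 for ndrg1a, 4.17 for ckmt1, 4.13 for cavin2a, -6.66 for col10a1a and -3.23 for cryba4. For all 3 factors they were 3.10 for irx4a, 2.72 for egr2b, 2.70 for anxa1b, 2.33 for rasd1, -3.91 for cavin2a, -3.42 for slc18a3a, -3.40 for bhmt, -3.30 for apobb.1 and -3.26 for pvalb6. Where a gene is listed at 0 in a whole group (cavin2a in the retina groups other than WT at 52 hpf, capn2l in retinas, crygmxl2 in WT retinas at 52 hpf, crygm2c in yng retinas at 36 hpf, slc18a3a in WT retinas at 36 hpf), the size rests on the offset of 16. The sizes for irx4a depend on it too, because yng retina replicates 2 and 3 at 36 hpf were near the floor.

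Among the fixed lists, the medians in the test of genotype by time in retina were -0.33 (progenitor), -0.15 (photoreceptor), -0.53 (amacrine, bipolar and horizontal cells), 0.30 (cell cycle), 0.24 (blood) and -0.027 (liver, gut and yolk). For genotype by tissue at 36 hpf they were -1.02 (ganglion cell), -0.31 (amacrine, bipolar and horizontal cells), -0.67 (synapse), 0.15 (cell cycle) and -0.54 (blood), and at 52 hpf -0.91 (ganglion cell), -0.18 (photoreceptor), -0.39 (amacrine, bipolar and horizontal cells), -0.75 (synapse), 0.37 (cell cycle) and 0.31 (lens). For time by tissue in WT they were -0.29 (Notch), 0.55 (ganglion cell), 0.19 (photoreceptor), 0.605 (amacrine, bipolar and horizontal cells), 1.23 (synapse), -0.35 (lens) and -0.35 (skin and skeleton), and for all 3 factors -0.12 (amacrine, bipolar and horizontal cells) and 0.23 (cell cycle).

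The 186 probe sets changed alike in all 4 genotype contrasts may hold variants inherited with the mutation, in addition to genes that depend on smarca4a, which the design does not separate. Of the genes placed on chromosomes, 14 of 453 on the smarca4a chromosome were among them, or 3.09%, against 99 of 8305 elsewhere, or 1.19% (odds ratio 2.64, one-sided Fisher's exact p = 0.00199), so linkage is a candidate explanation for part of them. By this share the smarca4a chromosome had rank 2 of 25, and the larger share of another chromosome cannot come from linkage to smarca4a. Those 14 lay no nearer to smarca4a than other measured genes of the chromosome, at a median of 195.5 genes against 112 (one-sided permutation p = 0.93), which argues against its immediate neighbourhood as the source. The fluidics station differed between the genotypes on every array and cannot be told apart from genotype. The hybridization spike-ins differed by a mean of 0.036 between stations, over all tissues and ages. In retinas at 52 hpf the spike-in bioB was 474.4, 257.9 and 203.7 in yng replicates 1, 2 and 3, against 408.2, 191.6 and 175.1 in WT. There bioC was also higher in yng in each replicate, while bioD and cre went both ways.

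The crystallin genes higher in yng retinas at 52 hpf may come from lens cells carried into the pools. If crybb1 came from lens alone, that share of lens would bring far more of cryba4, crygmxl2, crygm2c and bfsp2 than was seen. Their excess reached a median of at most 19.8% of that amount on any of the 3 arrays. This argues against lens as the whole source only if carried lens cells hold these transcripts in the proportions of the whole embryo. That was not tested. From the share implied by crygmxl2, crygm2c reached 65% of what lens would bring, so lens stays a candidate source for these genes. Replicate 3 stood far below the other two for crybb1 (289 against 1770 and 2130) and cryba4 (119 against 1000 and 892). At 36 hpf the log2 values of cryba4 in replicates 1, 2 and 3 were 9.98, 8.82 and 7.19 in yng retinas. In WT retinas of that age they were 7.35, 6.45 and 7.85, so yng replicate 3 was the lowest yng array at both ages. Expression of crystallins by retinal cells was not tested.

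The lower ganglion cell and synapse transcripts of yng retinas were set against poorer RNA and other tissue, and a delay was tested on all probe sets changed by at least 2-fold. The gapdh 3'/5' log2 ratio differed by a mean of -0.222 at 36 hpf (-0.465, 0.001 and -0.201 by replicate). By this 1 transcript there was no sign of poorer RNA in yng at that age, which does not exclude it. At 52 hpf the ratio differed by 0.359, and poorer RNA stays open for part of the change. The highest median of the muscle, skin, liver and blood lists at 52 hpf was 0.113. At 36 hpf the median by day was -0.039, 0.051 and -0.024 for the muscle list and -0.096, 0.182 and -0.024 for the skin list. Muscle and skin transcripts were nearly absent from WT retinas. Enough such tissue to lower the neuronal lists this far would raise both lists clearly, which argues against muscle or skin. The rise needed was not computed. Of 796 probe sets that differed by at least 2-fold at 52 hpf, 615 lay toward the WT level at 36 hpf, 37 lay the opposite way, and 144 did not pass in the WT time course. Of the 615, 241 lay beyond the WT level at 36 hpf. Of the 502 past 0.001 in both contrasts, 14 differed from WT in the direction of the WT time course. That is opposite to a delay for transcripts that move one way between the 2 ages. For such transcripts a delay could thus account for part of the 796 but not for all of them. With only 2 ages measured, a transcript that peaks or dips between them could differ in this way under a delay alone. The test therefore does not exclude a delay as the whole cause. Of the members lower at 52 hpf, 10 of 13 in the ganglion cell list and 13 of 13 in the synapse list rose with age in WT, and 1 in the former fell. In each list 4 of those that rose lay beyond the WT level at 36 hpf, and 12 and 9 of the 13 were already lower in yng at 36 hpf. A delay stays open for these lists. The contrasts share the WT arrays at 52 hpf, which alone gave r = -0.507 in simulated data against -0.605 observed, and a covariance of -0.017 against -0.208.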

How the results depend on the processing

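The setting without the array with a wash error and the array alone on its day was chosen after the data were seen; all others were set before the data were examined. Of 279 values of named genes, 263 past the threshold, and 270 list tests, none of the gene values reversed in any setting in which it was run (186 of the 279 without the dimmest 40% of probe sets, all in the others) and none of them lost its call with the replicate block, while the block ended 7 list calls and added 4. Gene calls ended in 11 values with a log offset of 1, 12 with only the groups of the contrast in the fit, 10 with backward elimination, 9 without variance moderation, 5 on the intensities as deposited, 4 with the day as a block, 6 without the doubted arrays and 106 of the leave-one-out values. List calls ended in 53 tests with an estimated correlation, 7 with fry, 6 with all probe sets of a gene, 5 as deposited, 5 without the doubted arrays and 39 of the leave-one-out tests. The 5 list results that reversed did so with fry, which does not compare a list with other genes, and were not called by camera: the SWI/SNF list, which holds smarca4a itself, in the genotype contrasts (adjusted p = 0.00754 and 0.00475 in retinas at 52 and 36 hpf, 0.000919 and 0.000132 in embryos), and the p53 list in WT retina against embryo at 36 hpf (0.0231). The cause was not tested, except that the counts at 2-fold follow from the stricter threshold. Signal near background limits what dim probe sets can show: a difference there depends on the offset.

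Counts of probe sets that moved by more than 1.5 times were as follows. With the replicate block the genotype contrasts gave 4818 and 2865 (retina, 52 and 36 hpf) and 2116 and 2247 (embryo), time gave 3893 in WT and 2775 in yng embryos, and the interactions gave 1406 (genotype by time in retina), 816 and 1971 (genotype by tissue at 36 and 52 hpf), 3210 (time by tissue) and 292 (all 3 factors). With the hybridization day as a block the values were 4770, 2793, 1458 and 2198 for genotype in the same order, 2724 for time in yng embryos, and 1353, 765, 1760, 2874 and 215 for the interactions. With backward elimination they were 5144, 4366, 3832 and 3681 for genotype, 7096 for time in yng retinas, 5685 and 5034 for time in WT and yng embryos, 1034 for genotype by tissue at 36 hpf and 3137 for time by tissue. With only the groups of the contrast in the fit they were 331 and 449 for genotype at 36 hpf in retina and embryo, 384 for genotype by time and 184 for genotype by tissue at 36 hpf. At 2-fold or more they were 796, 342, 212 and 155 for genotype, 1574, 1085, 374 and 232 for time (WT and yng retina, WT and yng embryo), 3965 and 3405 for tissue at 36 and 52 hpf, and 358, 235, 580 and 890 for the first 4 interactions. On the intensities as deposited tissue at 52 hpf gave 7043. Without the dimmest 40% of probe sets tissue gave 6997 and 6748 and the interaction of all 3 factors 75, and with a log offset of 1 the last gave 72.

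Leaving out 1 array at a time gave ranges of 2494 to 2579 and 1083 to 1452 for genotype in retinas at 52 and 36 hpf, 603 to 711 and 590 to 694 in embryos, 4838 to 5456 and 3318 to 3847 for time in WT and yng retinas, 1663 to 1853 and 787 to 1214 in WT and yng embryos, 10658 to 10988 and 10021 to 10317 for tissue at 36 and 52 hpf, 521 to 734 for genotype by time in retina, 288 to 507 and 836 to 935 for genotype by tissue at 36 and 52 hpf, 1567 to 1988 for time by tissue and 111 to 192 for all 3 factors. A group left with 2 arrays takes its spread from the other groups.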

Other observations

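The tests of the FGF and glucocorticoid lists were chosen only after the result was seen; those of the brain list were set before its result was seen, on a list written after the other results.

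Several genes of FGF signalling, which patterns the eye and brain, were higher in yng retinas. At 36 and 52 hpf the feedback inhibitor spry4 differed by 1.51 and 0.96, il17rd by 1.01 and 1.72, etv5b by 0.98 and 1.35, and fgf8a by 1.54 and 1.75, while the phosphatase gene dusp2 differed by -2.04 at 52 hpf. These genes were chosen after their values were seen. Of 15 listed members other than fgf8a and etv4, 6 were higher and 1 lower at 36 hpf (median 0.37, camera adjusted p = 0.00346, and adjusted p = 0.00945 with an estimated correlation). At 52 hpf 4 were higher and 3 lower (median 0.12, adjusted p = 0.724). The list was completed after values of most members had been seen. Some receptor genes that did not pass were left out, while fgfr4, which did not pass either, was kept. Neither test therefore decides whether the group moved. Brain tissue kept on the yng retinas could bring such transcripts. At 36 hpf 35 genes of brain regions outside the eye gave a median of -0.06 (4 higher, among them pax8 at 0.94 and zic2a at 0.72, and 1 lower; adjusted p = 0.836), and at 52 hpf 0.20 (6 higher, among them en2b, and 2 lower; adjusted p = 0.393). The gene pax2a, not on that list, gave 1.302 (adjusted p = 0.000453) and 1.45 at 36 and 52 hpf in 1 probe set, and 0.25 (adjusted p = 0.529) and 0.53 (adjusted p = 0.0669) in the other. The genes pax2a, pax8 and zic2a were chosen after their values were seen. The bound on the median set in advance for 36 hpf was met, but it does not decide where members go both ways, so brain tissue stays open at both ages.

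Of genes that respond to glucocorticoids, fkbp5 differed by -1.99 and -2.65 and klf9 by -1.82 and -2.05 in yng embryos at 52 and 36 hpf, chosen after their values were seen. The cortisol-inactivating enzyme gene hsd11b2 was lower in all 4 genotype contrasts, at -2.08 in retinas and -1.26 in embryos at 36 hpf. The 20 genes of the glucocorticoid list other than fkbp5 and klf9, among them hsd11b2, gave no group difference past the threshold, with a median of 0.07 at 36 hpf (2 higher, hsd11b2 lower, adjusted p = 0.331) and 0.01 at 52 hpf (1 higher, hsd11b2 lower, adjusted p = 0.878). That list too was completed after values of many members had been seen, so a change of the response as a whole stays open.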
